A study of Xenopus laevis with 2 samples.

How the data were processed

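Dissociated Xenopus laevis animal cap cells treated with BMP2 and cycloheximide were compared with cells given cycloheximide alone on 2-colour cDNA arrays of 2 designs. Per the labels, the treated RNA was marked with Cy5 and the control RNA with Cy3, slides were read with a GenePix scanner, and results were in triplicate. How the 3 results were combined, how background was treated and how channels were normalised is not given in the sources used here. 1 column of values per array set was analysed, so the groups have no replicates, no p-value across clones was computed, and the precision is limited by the number of arrays.

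The deposited values are signed fold changes, that is, a ratio where it is at least 1 and minus its reciprocal otherwise. This reading comes from the values: both signs occur, and in clone wells only 6 nonzero values on array set 1 and 41 on array set 2 have a size under 1. The values do not behave as logarithms, since they range from -34.2 to 46.5 on array set 1 and from -261.0 to 147.1 on array set 2. The direction is called likely because the dyes are stated and the numerator is not. The authors' centring is unknown: array medians were -0.05 and 0.20 log2 units.

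Each value of size 1 or more was turned into a log2 fold, keeping its sign, and centred on the median of the clone wells of its array. Values of exactly 0 and values under 1 in size were left out, which kept 21066 and 19884 of 21120 clone wells. The plate whose IDs carry no plate number was left out of these counts. That choice was made after the IDs were seen, and what its wells hold is not stated. Clones at least 2-fold from the median were counted in each direction, without a test. The spread over clones is a robust SD, 1.4826 times the median absolute deviation. Array sets were never pooled, since 0 probe IDs occur on both.

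Floor steps were searched for among values of each sign with a size under 1 or over 2. The plate without a plate number was included in this search. Steps were read as the value of 1 intensity unit in wells whose other channel was at 0, which no label states. Steps between 0.25 and 1.6 were tried, and 1 whose multiples were mostly divisible by 2 or 3 was enlarged by that factor. A step was accepted when at least 5 values lay on its whole multiples within a relative 4e-06, and at least 1.5 times as many as in the best of 10 searches of values moved at random by up to 0.5%. It also had to hold 10% as many values as the first step. Steps that were simple fractions or quotients of others were not used to mark clones. The search was written and its limits revised after the values were seen. It gave 6 steps on array set 1 and 4 on array set 2. The weakest, on array set 1, had 6 values against 4 after moving, exactly at the limit. Clone wells were then counted as on a step within a wider relative tolerance of 1e-05. They numbered 51 on array set 1 and 1383 on array set 2 (51 and 1382 within 4e-06), where steps shifted at random held at most 6 and 4 wells per sign. The scripts were tested on simulated data of 21120 clones per set. All 6 simulated scalings of a set modelled on array set 1 and all 4 of a set modelled on array set 2 were found, with 0 false steps. The simulated sets held 1174 and 1569 wells with 1 channel at 0. The real steps of array set 1 rested on only 6 to 18 values each, with the plate without a plate number included. Whether steps that sparse are found, or are false, was therefore not tested. The simulated scalings also stayed below the largest real steps, and fewer searches of moved values were run. Only 60.2% and 71.6% of the simulated wells with 1 channel at 0 were marked, so leaving out marked values removes part of them. The share marked in the real sets is not known. Every one of the 39 and 35 bright, unmarked simulated clones changed by 1.5 log2 units passed 2-fold. The noise between simulated clones was set below the real robust SD, and no plate shifts were simulated. This result therefore does not give the share of such clones found on the real arrays.

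Position classes and plates were examined after the values were seen. The period of 8 rows and 4 columns was picked after several groupings of wells had been compared on the same data, so its permutation tests, each with 100000 permutations, describe a pattern already noticed. Plate and class were centred in turn for 5 rounds. Correlations used Pearson's r and Spearman's rho, with two-sided permutation tests where a p-value is given.

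Before the data were examined, gene lists, gene values over probes, the spread between probes of a gene and genes on both arrays had been planned, together with a rule for named genes. None could be computed, because none of the 43008 probe IDs matched the 44456 genes of the RefSeq table of assembly Xenopus_laevis_v10.1. The fixed rule for that case was to name the 2 highest and 2 lowest probe IDs per array, leaving out zeros and repeated values. Values on a floor step were left out as well, as a form of repeated value. Other settings fixed at that time were no centring, thresholds of 1.5-fold and 3-fold, leaving out floor values, and a threshold of 3 robust SD. Keeping the control plate, centring plates or position classes or both, leaving out the first 10 plates, a range of 2-fold to 4-fold, and combinations of these were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.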

Results

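Animal cap cells are the ectodermal cells at the upper pole of the Xenopus laevis blastula, and they take on different fates according to the growth factors they meet. Caps were cut from stage 8 to 9 embryos and dissociated, so that BMP made by the cells themselves was diluted. The cells then received the growth factor BMP2 together with cycloheximide, a blocker of protein synthesis, or cycloheximide alone. RNA was taken at stage 10.5 to 11. The comparison asks which transcripts respond to BMP2 without the making of new protein. Treated RNA carried Cy5 and control RNA carried Cy3, and both were hybridised together to cDNA arrays of 2 designs, called array set 1 and array set 2 here. Each set gave 1 column of 21504 values: 21120 from library clones on 55 plates of 384 wells, and 384 from a plate without a plate number in its IDs, here called the control plate. With 1 column per set there was no replicate error, and no value below has a p-value for the effect of BMP2. The number of arrays limits the precision.

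The values were signed fold changes. A positive value was likely a clone with more transcript after BMP2, because the labels give Cy5 to the treated cells and describe a search for genes raised by treatment. The labels do not name the numerator of the ratio. They give the same dye to the treated cells throughout, so a difference between the dyes cannot be told apart from an effect of BMP2. With Cy3 as numerator, every higher and lower below would change places, and the shares of higher clones given for the 2 sets would become 85.3% on array set 1 and 34.8% on array set 2. Of the 43008 probe IDs, 0 matched a name in the gene table used, so clones are given by ID and no gene or gene group is described.

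On array set 1, more clones lay below the array median than above it at the 2-fold threshold. Of 21066 clones with a fold, 156 (0.741%) were at least 2-fold higher and 905 (4.30%) at least 2-fold lower, which was 5.80 lower clones for each higher one. The middle of the distribution was narrow, with quartiles at -0.25 and 0.21 on the log2 scale around the median. Its tail was longer on the lower side, with the 1st percentile at -2.08 and the 99th at 0.88. The array median was -0.05 before centring, a fold of 0.968. The robust SD over clones was 0.337 log2 units, so the threshold stood 2.96 robust SD from the median. This spread is between clones, not between repeats of a clone.

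The clones named by the fixed rule, with an exclusion added later, were XL035b14 and XL052a13 on the higher side and XL052i05 and XL047i06 on the lower side. XL035b14 had a deposited value of 42.8 and a centred log2 value of 5.47, and XL052a13 had 14.5 and 3.91. XL052i05 had a deposited value of -34.2 and a centred log2 value of -5.05, and XL047i06 had -26.6 and -4.68. The search for floor steps was written after the values were seen, and the highest value of array set 1, 46.5, was not named. Values on a floor step, a pattern described for array set 2 below, had been left out before these clones were named. They made up 16 of the 156 higher clones (10.3%) and 27 of the 905 lower clones (2.98%) of array set 1, but 5 of the 7 positive and 6 of the 47 negative values of size 10 or more, and 1 of the 2 positive and 2 of the 6 negative values of size 20 or more. XL035b14, XL052a13, XL052i05 and XL047i06 are of such sizes, and they are given as deposited values, not as measured folds of that size.

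On array set 2, more clones were higher than lower. Of 19884 clones with a fold, 2483 (12.49%) were at least 2-fold higher and 1328 (6.68%) at least 2-fold lower, so 65.2% of the 3811 clones beyond the threshold were higher, against 14.7% of 1061 on array set 1. The share rose to 75.5% when plates and well positions were centred. It fell to 46.4% of 1755 when only clones between 2-fold and 4-fold were counted, so the majority of higher clones rested on values beyond 4-fold. In that same range it was 61.2% of 1204 once floor-step values were also left out and plates and positions centred. The higher side held a broad shoulder, with the 95th percentile at 3.47 and the 99th at 5.05, while the 5th was at -1.16 and the 1st at -2.97. The array median was 0.20 before centring, a fold of 1.15, and the robust SD was 0.534, which put the threshold at 1.87 robust SD.

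Many of the large values on array set 2 did not behave as folds. They lay on whole multiples of a few fixed steps, called floor steps here, as values would if 1 channel read 0 and the scaled intensity of the other stood in place of a ratio. The 2 main positive steps were 0.845, with 1089 values on it, and 2.30, with 139, where searches of randomly moved values found at most 7. These searches and counts included the control plate. Of the 2483 higher clones, 1155 (46.5%) were on such a step, and of the 1328 lower clones, 142 (10.7%). Among values of size 10 or more, 808 of 1187 positive and 106 of 153 negative ones were on a step. Without floor-step values, 1368 clones were higher and 1091 lower. Values of exactly 0, which hold no fold, made up 5.66% of clone wells on array set 2 (1195 wells) and 0.227% on array set 1 (48 wells).

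The higher clones named by the rule were XL068o08, at a deposited value of 75.2 and a centred log2 value of 6.04, and XL100e16, at 74.97 and 6.03. The lower ones were XL074f23, at -79.2 and -6.50, and XL063c04, at -78.3 and -6.49. Floor-step values had again been left out before naming, and the extreme values of 147.1 and -261.0 were not named. The 4 named clones are of a size at which most values were on a step, 74 of 96 positive and 30 of 34 negative ones at 50 or more. Sums over several arrays with a channel at 0 would escape the search. The 4 clones are given as deposited values, not as measured folds of that size.

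**Figure D1:**
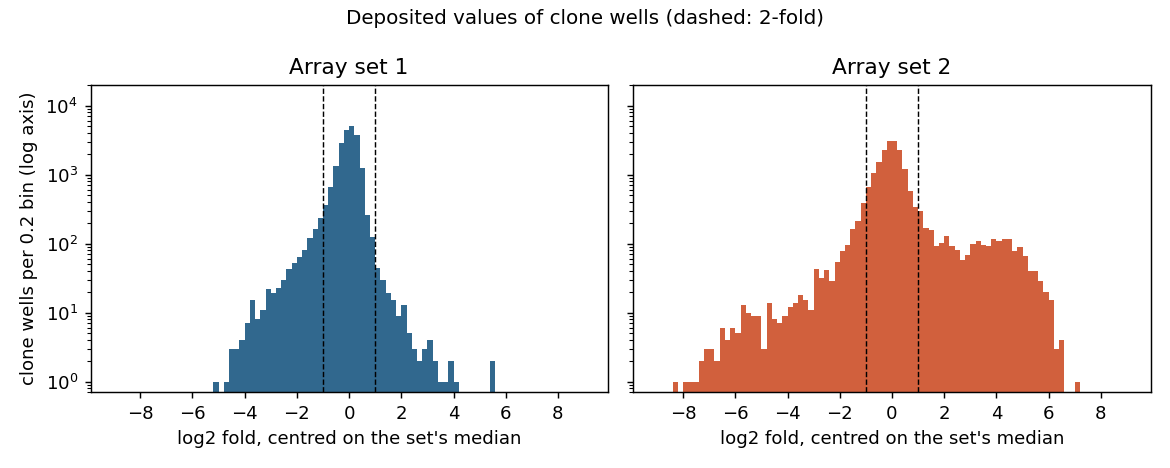
Number of clone wells (log axis) per bin of 0.2 log2 units of the deposited fold, centred on each set's median, with 2-fold marked by dashed lines. Array set 1 has its longer tail on the lower side (905 lower, 156 higher clones) and array set 2 a broad shoulder on the higher side (2483 higher, 1328 lower), where 1155 values lie on floor steps.

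The values also differed between clone plates. The first 10 plates of array set 2 had a typical plate median of -0.46 against 0.05 for the other plates. Of their clones, 20.9% were at least 2-fold lower against 3.74% on the other plates. The share at least 2-fold higher was also larger on the first 10 plates, at 14.827% against 12.004%. The lowest plate median was -0.60, at plate 59. On array set 1 the same split gave plate medians of -0.07 and 0.01, lower clones of 7.80% and 3.52% and higher clones of 0.861% and 0.714%. Plate 1 was lowest at -0.31. The split at 10 plates was chosen after the values were seen.

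**Figure D2:**
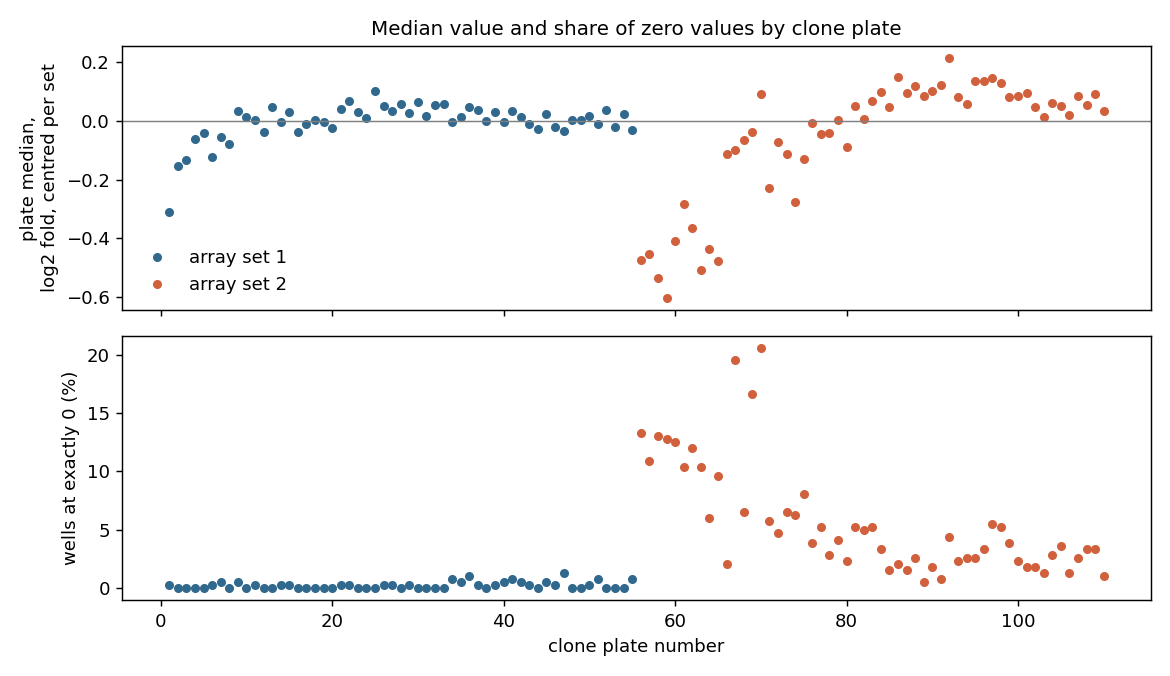
Median centred log2 fold (top) and percent of wells at exactly 0 (bottom) of each of the 55 clone plates per array set, 1 point per plate. The first 10 plates of array set 2 have medians near -0.46 and 11.5% zeros at the median, against 0.05 and 3.39% for its other plates.

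Well position within a plate was a further source of difference. Grouping wells by row modulo 8 and column modulo 4 gave 32 position classes, whose medians ran from -0.47 to 0.35 on array set 2 and from -0.18 to 0.19 on array set 1. The classes took 87.3% of the variance of the 384 well medians on array set 2 and 73.0% on array set 1, and 32 blocks of neighbouring wells took 8.40% and 39.2%. In 100000 permutations of wells the classes took at most 18.8% and 18.6% (permutation p = 1e-05 in each set, the smallest possible). On array set 1 the blocks of neighbouring wells also took more than 18.6%. There this p-value does not set the period apart from other spatial groupings. Over single clones, class took 16.04% of the rank variance on array set 2 (0.156% by chance) and 6.81% on array set 1 (0.147% by chance). After both plate and class were centred, the robust SD was 0.401 on array set 2 and 0.321 on array set 1, and 2488 higher and 807 lower clones were beyond 2-fold on array set 2. On array set 1 the counts were 159 and 853. All 8 named clones stayed on their side, with log2 values from 3.82 to 6.03 for the higher ones and from -4.78 to -6.29 for the lower ones. Having been picked as extremes, these clones could not have changed side through shifts as small as those of plates and classes.

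**Figure D3:**
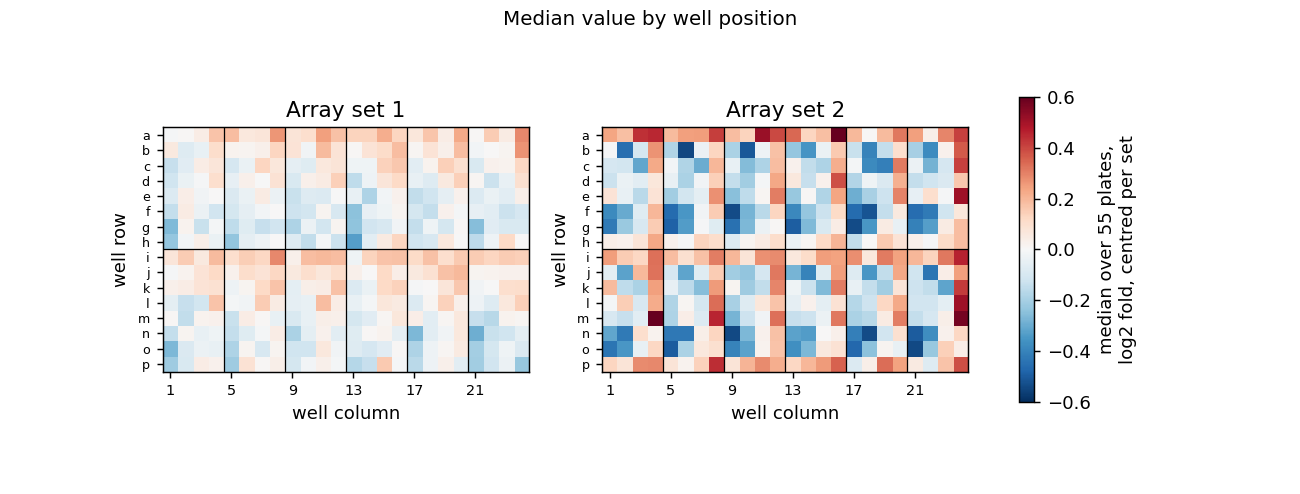
Median centred log2 fold over the 55 plates at each of the 384 wells, by well row and column, for each array set, with lines every 8 rows and 4 columns. The same pattern recurs in each block of 8 rows by 4 columns, with class medians from -0.47 to 0.35 on array set 2 and from -0.18 to 0.19 on array set 1.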

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

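Leaving out floor values was fixed before the data were examined, but the search that marks them, the use of these counts as tests of explanations, the other tests in this part and the limits they were read against were chosen after the results had been seen. The limits for the lean of the calls, the ratio of spreads and the number of channel scalings were changed once their values were known.

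The direction of the clones beyond 2-fold differed between the array sets by 50.4504 percentage points (14.7% higher on array set 1, 65.2% on array set 2), and the difference was not tested, as each set has 1 column. Shifts of plate and position medians as the whole cause are argued against by a difference of 59.8 points after both were centred. Centring moves medians only, so effects of plate or position on the far values stay open. On array set 1, the marked floor-step values do not account for the lean to lower, which stood at 13.8% higher without them. Only 16 of 156 higher and 27 of 905 lower clones were marked. The marking is incomplete, so a part played by unmarked wells with a channel at 0 stays open. On array set 2, wells with a channel at 0 may account for part of the lean to higher. The share was 55.6% without floor-step values. It was 46.4% between 2-fold and 4-fold, a range in which floor-step values were kept, so that value does not test these wells. With shifts centred, however, the share was 75.5% with floor-step values and 69.0% of 2029 without them (61.2% without them in the narrower range). As the marking is incomplete, this stays open too. A different response of the clones on the sets cannot be told apart from a difference between the hybridisations, because 0 probe IDs are on both sets.

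Values repeated with well position every 8 rows and 4 columns. The medians of the 32 classes from odd and from even plates correlated at r = 0.958 on array set 1 and 0.978 on array set 2 (permutation p = 1e-05 for each r, the smallest possible). Spearman's rho was 0.936 and 0.980, and was not tested. Other clones sit in the same wells of other plates, so clone content is argued against by this r of 0.958, and an effect of the place where a spot was printed is a candidate explanation. The class medians of the sets correlated with each other at r = 0.610 (permutation p = 0.00019; rho = 0.580, p = 0.00063), and at 0.489 without the 2 classes farthest from the median of array set 1. Which print tip or array block each well belongs to is not given in the sources used here.

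The values of array set 2 spread wider, with a ratio of robust SDs of 1.58. Plate and position shifts account for part: the ratio was 1.25 after they were centred, and 1.11 when floor-step values were left out too. The ratio of 1.25 had a 95% interval of 1.15 to 1.35 over 1000 draws of plates. Plates of a set share its hybridisations, so the interval covers the choice of plates, not a repeat of either set. Weaker signal on array set 2 is a candidate explanation, as 5.66% of its clone wells were exactly 0 against 0.227%. Whether fewer hybridisations were combined on array set 2 was left undecided by 4 channel scalings there against 6 on array set 1 (5 at the limits of array set 2), since an array without zeros leaves no step and the labels state 3 results for both sets; a wider response of its clones was not tested.

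On the control plates, which were left out of the main counts, a larger share of wells lay beyond 2-fold than among the clones. The share was 29.6% of 358 wells on array set 1, against 5.04% of clones, and 39.5% of 311 wells on array set 2, against 19.2%. Floor-step values were kept in all of these shares. Values of exactly 0 were also more common on the control plates, at 4.17% against 0.227% on array set 1 and 18.75% against 5.66% on array set 2. Whether wells with a channel at 0 account for the larger shares was not tested.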

How the results depend on the processing

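The alternatives that centre plates or position classes, leave out plates, keep the control plate or limit the range were chosen after seeing the data; the others were planned. On array set 1, lower clones outnumbered higher ones under every alternative run. The counts moved by more than 1.5 times only with the threshold, to 586 higher and 2008 lower at 1.5-fold and 63 and 394 at 3-fold. On array set 2, the higher share was 52.9% at 1.5-fold (3105 lower), 76.6% at 3-fold (571 lower) and 76.8% beyond 3 robust SD (563 lower). It was 75.5% with plates and classes centred (807 lower). Without the first 10 plates 675 clones were lower. Without floor-step values 1368 were higher, and with plates and classes centred as well, 1399 higher and 630 lower. The direction turned only between 2-fold and 4-fold, where 815 were higher and 940 lower (46.4% higher); with floor-step values left out and plates and classes centred there, 737 were higher and 467 lower. Apart from the thresholds and the sets of wells counted, the cause of these moves was not tested. The other 58 counts and shares stayed within 1.5 times or 10 percentage points, and each named clone moved by less than 1 robust SD of its array. Centring plates and classes lowered the robust SD from 0.534 to 0.401 on array set 2 and from 0.337 to 0.321 on array set 1. Genes in place of probes, gene lists, genes on both arrays, the spread between probes of a gene and their alternatives were not run, for lack of gene names. No paired analysis was possible because each array set has 1 column and no test. The 5.66% of clone wells at exactly 0 on array set 2 gave no fold, and signal over background was not measured here.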

Other observations

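The comparisons and groupings in this part were chosen after the values were seen. On the control plate of array set 1, the first 8 rows fell apart by column. The 48 wells in columns with remainder 2 modulo 4 had a median of 0.22 log2 units and an SD of 0.065, and ran from 0.07 to 0.39. The next column class had a median of 0.15 and an SD of 0.112, and in both classes 0 of 48 wells lay beyond 2-fold. The first column class had a median of -0.44 and an SD of 1.52 over its 44 wells with a fold. The last class had a median of -0.52 and an SD of 0.618, with 8 of 48 wells at least 2-fold lower. The other 8 rows did not show this: there the SDs of the 4 column classes ran from 1.08 to 1.67, and 46.8% and 48.9% of the wells with a fold of the classes that were narrow in the first rows lay beyond 2-fold. On array set 2 the SDs of the column classes in the first 8 rows ran from 1.096 to 1.61. The SDs are over wells, whose content is not stated.

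On array set 2, plates with more wells at exactly 0 had lower medians (r = -0.590, permutation p = 4e-05, adjusted 8e-05; rho = -0.582, permutation p = 1e-05, the smallest possible, adjusted 4e-05; 55 plates, 4 tests adjusted together). Without the 2 plates farthest from the median share of zeros r was -0.776. Among the plates after the first 10, r was -0.281 over 45 plates, and -0.381 without plates 67 and 70, which were farthest from the median share of zeros (rho -0.331 and -0.339). These later values were not tested. On array set 1 r was 0.021 (permutation p = 0.88, adjusted 0.88) and rho 0.041 (permutation p = 0.76, adjusted 0.88).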
